A study of Mus musculus with 10 samples.

How the data were processed

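Cortical midline tissue of mouse embryos on embryonic day 14.5 was dissected for all libraries, per the labels' protocols. For ChIP-seq, tissue was fixed with ethylene glycol bis(succinimidyl succinate) and then formaldehyde, sonicated and precipitated with an Rcor2 antibody or an IgG control, per the labels, and input libraries were made as well. RNA libraries were made with an Illumina TruSeq kit, which the sample protocol calls an RNA kit and the series design a total RNA kit, so the kind of RNA selection is open. Groups and replicate numbers were taken from the sample titles: 2 libraries each of Rcor2 ChIP, IgG ChIP, input, control RNA and cKO RNA. The submitters' processing notes name HISAT2 2.1.0, Trim Galore and the mouse genome build mm10, without saying for which step or library. The gene counter, the annotation, strand use, the normalization and the peak caller's settings are not given in the sources used here.

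Per the file headers, the RNA table holds normalized counts, a signal per gene and library. In the deposited columns, 100% of values were whole multiples of 1 step per column within a tolerance of 1e-04, as read counts divided by 1 factor per library are, and whole reads per gene were recovered on that basis. The libraries held 30270598 and 27674987 such reads (controls 1 and 2) and 28309925 and 29783893 (cKO 1 and 2), and the 10 most abundant genes took 4.41 to 4.59% of them. The table holds 16338 genes. Of these, 23 had names turned into dates by a spreadsheet and were left as they stood, and 97.7% of symbols were in the gene name table. The authors' deposited log2 fold changes with standard errors, a test score and p-values (adjusted p-values missing for 3805 genes) sit beside the counts, per the file headers; their column names are those of a DESeq2 results table. The authors' deposited mean count differed from the mean of the 4 columns (median ratio 1.016), which leaves open which size factors that test used.

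Per the file headers and peak names, the authors called peaks on the Rcor2 libraries against IgG, with column names of a MACS peak table. Each peak has a pileup, a fold enrichment over the IgG background and, in 2 columns whose deposited headers were spoiled, values that by place and range are −log10 of p and of q. Peak numbers in the names run to 7106 and 6995 peaks are listed, so 111 had been removed. The deposited table also gives each peak's height (coverage) in each of the 6 ChIP and input libraries, a location class and a gene name. The rule behind the classes and gene names is not given in the sources used here. Heights are whole numbers with no scaling for depth that the values show, and no library totals were analysed here.

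The RNA comparison fitted limma-trend (limma 3.58.1, R 4.3.3) to log2(normalized count + 1), with no replicate block, two-sided, over the 14324 genes with a mean of at least 10 normalized counts; 2014 genes were left out. With 2 libraries per group the residual degrees of freedom were 2 and the prior degrees of freedom 6.21; an exact permutation test of 2 against 2 cannot go below p = 0.333 for a single gene. p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Log2 changes are on the log2(value + 1) scale, which understates changes of low genes. Fixed lists (16 of pathways and cell states and 10 of marker genes) were tested with camera at a preset correlation of 0.01, adjusted over 25 lists; none of the 15 mitochondrially encoded genes was in the table, so that list had no value. In all, 13 lists passed, 6 upward and 7 downward. With camera's correlation estimated from these 4 libraries 0 passed (2 at an unadjusted p under 0.05). By fry, which asks whether a list's genes move one way on balance, 0 passed (12 at an unadjusted p under 0.05, smallest adjusted p 0.0509). Bound genes were those that the authors named for any peak, 2993 of the tested genes. Overlaps were tested with Fisher's exact test (two-sided) over tested genes; the 18 overlaps of peak sets with changed genes were adjusted together, and the lists over all lists. Gene spans came from RefSeq (GRCm38.p6, the assembly of mm10) and were known for 96.9% of tested genes; histone symbols had no span there, so the span check of the histone list is void, as it is for the lists without a peak gene. Intervals of shares of peaks are 95% Clopper-Pearson and cover counting error only. Ratios of heights had 0.5 added to both sides. Peak heights are not read counts, so the count test that had been planned for Rcor2 against IgG was not made. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

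Named genes followed a rule set before the data were examined: Rcor2; the 12 largest rises and 12 largest falls among called genes with a mean of at least 50, non-overlapping groups, no predicted name and no sex linkage; up to 4 called members of each list by smallest adjusted p, or its 2 most abundant members; the 8 called peak genes with the smallest adjusted p; the 10 highest-scoring peaks; and the strongest peak of each named list gene. Slit2, Gli2, Gli3, Scube1, Ptch1, Kdm1a, Snap25, Tubb3, Gria2, Col3a1, Igf2, Tenm4, Auts2, Nfia and all genes of the families described after the report were named after their values had been seen. Some genes that the rule names are not reported here. The lists overlap: for example 6 pan-neuronal genes are in other lists too.

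The gene tests and camera were tried on simulated data; fry and Fisher's exact test were not. Negative binomial counts were drawn for the 14324 tested genes from their means, the trended dispersion and the scaling of the 4 RNA libraries, with 200 genes changed. At 1.5-, 2- and 4-fold, limma recovered 61.2%, 86.6% and 100% of changed genes, and 15 of its 180 calls were false; edgeR 4.0.16 recovered 62.7%, 88.1% and 100%. Camera was run on each simulated list alone, at an unadjusted p under 0.05. It called 2.5% of 40 unshifted lists of 30 genes and 100% of lists shifted by 0.3 on the log2 scale. With its correlation estimated it called 95% of the shifted lists. The simulated genes were drawn independently of each other. In the real lists the correlation that camera estimated ranged from -0.143 (astroglia) to 0.937 (meningeal fibroblasts). It was 0.644 for pan-neuronal and 0.646 for cell cycle genes. These rates therefore do not carry over to lists of correlated genes, nor to calls at a p adjusted over 25 lists.

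The alternatives set before the data were examined were the replicate number as a block, other pseudocounts and filters, TMM factors or quantile normalization on top of the deposited values, leaving out each RNA library, edgeR's quasi-likelihood test on the recovered reads, the authors' deposited test, other thresholds, the other set tests, stronger or stricter peaks, and matching on expression. On the recovered reads edgeR called 1742 genes, 1654 of them shared with limma, and the authors' deposited table called 1587, 1504 of them shared. Promoter or gene body peaks alone, peaks above or not above input, peaks ranked by Rcor2 over input within each replicate, gene span in the model (also for gene families), leaving out ChIP libraries, summed heights, edgeR with the block, removal of genes high in cKO replicate 1 and list counts without each library were added after seeing the data.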

Results

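The series measured where Rcor2 lies on chromatin and which transcripts change when Rcor2 is deleted in the cortical midline of mouse embryos on embryonic day 14.5. Rcor2 (REST co-repressor 2) is a member of the CoREST family, scaffold proteins that join the histone demethylase Kdm1a (LSD1) and histone deacetylases into a repressor complex. The chromatin data came as 1 table of peaks with a height in each of 6 libraries, and the transcript data as 1 table of normalized read counts in 4 libraries. For chromatin immunoprecipitation with sequencing (ChIP-seq) of wild-type midline, 2 libraries were made with an antibody to Rcor2, 2 with control IgG and 2 from input chromatin. For RNA-seq, 2 control libraries came from embryos with both Rcor2 alleles floxed, and 2 conditional knockout (cKO) libraries from floxed embryos that also carried Emx1-iCre, a recombinase active in progenitors of the dorsal telencephalon. The RNA libraries held 30270598 and 27674987 recovered reads in the controls and 28309925 and 29783893 in the cKO. The 2 libraries of each genotype differ in the expression of sex-linked genes (below), so they came from different animals. Nothing in the labels gives the litters or any pooling, and each limma p-value of a gene measures only the spread between these libraries. Fisher's exact test counts genes as independent units, and camera's preset correlation of 0.01 takes the genes of a list as nearly independent. The p-values of these 2 tests therefore do not measure the spread between animals.

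The first comparison asked how far the deleted gene itself differed between control and cKO midline. Rcor2 (mm10 chromosome 19, 7267394 to 7275225) had normalized counts of 7901 and 7257 in the controls and 6363 and 6840 in the cKO, a mean of 7579 ± 455 against 6602 ± 337 (SD, n = 2 each). The log2 change was -0.20 (SE 0.057), with a limma adjusted p of 0.0541, which did not pass the threshold of 0.05. In the authors' deposited table the log2 change was -0.19 (SE 0.067) with an adjusted p of 0.0444. Without cKO replicate 2 the log2 change was -0.25 with a limma adjusted p of 0.00943. The sources used here do not say which exons were floxed, and a count over the whole gene does not show whether the deleted exons were read, so this value is a weak check of the genotype labels. Among 20 measured members and partners of the CoREST-LSD1 complex, 2 rose, 1 fell and 17 did not pass. Zfp217, a zinc finger partner of the complex, rose (log2 0.53, SE 0.055, limma adjusted p 0.00387), as did Rest, the repressor of neuronal genes in non-neuronal cells (log2 0.26, SE 0.072, limma adjusted p 0.0494). Insm1, a transcription factor of neurogenic progenitors, fell (log2 -0.21, SE 0.057, limma adjusted p 0.0425). Adjusted over the list alone, 3 members rose and 2 fell. Without cKO replicate 2, 5 members rose and 2 fell, and without any 1 of the other 3 libraries 1 rose and 0 fell. Kdm1a had a log2 change of -0.09 (limma adjusted p 0.204). The list did not pass against other genes (camera adjusted p 0.528), with a median of -0.01, a mean of 0.03 and an upward test direction. Rest did not pass with edgeR (adjusted p 0.0779), with quantile normalization, with a replicate block, without either control or without cKO replicate 1. Insm1 did not pass after TMM scaling or quantile normalization, in the authors' test, without either control or without cKO replicate 1.

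Across the genome, 2070 of 14324 tested genes (14.5%) differed between cKO and control at a limma adjusted p under 0.05, of which 882 were higher and 1188 lower in the cKO. Most changes were small: the median absolute log2 change of these genes was 0.35, and 118 changed at least 2-fold, 68 upward and 50 downward. The largest rises among well-measured genes were in Crabp2, a cellular retinoic acid binding protein (log2 2.20, SE 0.17, limma adjusted p 0.00244), and Ucp2, a mitochondrial carrier (log2 2.04, SE 0.11, limma adjusted p 0.000823). Crabp2 went from 152 ± 17.9 to 711 ± 179 normalized counts and Ucp2 from 280 ± 43.6 to 1153 ± 55.9 (SD, n = 2 each). Col1a1, Slc5a7, Fndc3c1, Dennd1c, Robo3, Syne3, Doc2b, Dmrt1, Sypl2 and Capn6 followed, with log2 changes from 2.01 down to 1.45. Slc5a7 encodes the choline transporter and Robo3 a receptor of commissural axons, with log2 rises of 2.00 (SE 0.34) and 1.60 (SE 0.26). The largest falls were in Mc4r, a melanocortin receptor (log2 -1.65, SE 0.24, limma adjusted p 0.00711), and Pxdc1 (log2 -1.42, SE 0.18, limma adjusted p 0.00506). Mc4r went from 202 ± 4.85 to 66.3 ± 25.3 normalized counts (SD, n = 2 each). Dmrt2, Ntm, Pttg1, Col19a1, Ube2ql1, C1ql3, Npas1, Alas2, Slc6a11 and Pou3f1 followed, with log2 changes from -1.41 to -1.18. Ntm encodes a neuronal adhesion molecule of the IgLON family, C1ql3 a secreted synaptic organizer and Pou3f1 a transcription factor of upper-layer neurons. The count changed with the library left out: it was 172 without control replicate 1, 127 without control replicate 2, 1460 without cKO replicate 1 and 3463 without cKO replicate 2. With a control left out, the residual spread is that between the 2 cKO libraries alone. All 2070 genes kept their sign, but this was fixed in advance. The 2 groups did not overlap in value for any called gene, so leaving out a library could not change a sign. Of the 94 named genes that passed, 53 did not pass without control replicate 1, 62 without control replicate 2 and 5 without cKO replicate 1, and none changed sign.

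Genes of differentiated neurons were lower in the cKO. Of 25 measured pan-neuronal genes, 21 fell, 0 rose and 4 did not pass, with a median log2 change of -0.40; adjusted over the list alone, 23 fell. Mapt, which encodes the microtubule protein tau, went from 14797 ± 226 to 8793 ± 783 normalized counts (SD, n = 2 each; log2 -0.75, SE 0.062, limma adjusted p 0.00263). Rbfox1, a neuronal splicing factor, fell by 0.77 on the log2 scale (SE 0.065), the kinase gene Mapk10 by 0.65 (SE 0.073) and Stmn2, a stathmin of growing axons, by 0.62 (SE 0.070). The list was lower than other genes with camera's preset correlation (adjusted p 1.09e-15) but not with its correlation estimated (adjusted p = 0.409 with an estimated correlation). Of 45 genes that Rest is known to repress outside neurons, 33 fell, 0 rose and 12 did not pass, with a median of -0.39; adjusted over the list alone, 33 fell and 1 rose. As a set, these genes differed from the rest (camera adjusted p 2.19e-17; adjusted p = 0.372 with an estimated correlation). The synaptotagmin gene Syt4 fell by 0.56 on the log2 scale. The 2 lists share Stmn2, Snap25, Tubb3 and Gria2. Against both controls, the pan-neuronal median was -0.47 in cKO replicate 1 and -0.30 in cKO replicate 2, and that of the Rest-repressed genes -0.46 and -0.32. Without control replicate 1 and without control replicate 2, 7 and 6 pan-neuronal genes fell, and 7 and 6 of the Rest-repressed genes.

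Markers of cortical projection neurons fell more often than they rose. Of 21 measured upper-layer and callosal genes, 10 fell, 1 rose and 10 did not pass (median -0.25); adjusted over the list alone, 12 fell and 4 rose. Rorb fell by 1.10 on the log2 scale (SE 0.12), Mef2c by 0.60 (SE 0.077) and Pou3f2 by 0.54 (SE 0.068), whereas Dkk3, which the hem list also holds, rose (log2 0.31, SE 0.045). Set against all other genes, the upper-layer list had a camera adjusted p of 0.000533 (adjusted p = 0.372 with an estimated correlation). Of 21 deep-layer genes, 10 fell, 2 rose and 9 did not pass (median -0.14); adjusted over the list alone, 10 fell and 3 rose. Ldb2 fell by 1.02 on the log2 scale (SE 0.15), Cdh13 by 0.57 (SE 0.082) and Sox5 by 0.33 (SE 0.046), and the nuclear receptor Nr4a2 rose by 0.70 (SE 0.10). The camera adjusted p was 0.00609 for the deep-layer list, and the adjusted p = 0.372 with an estimated correlation. Of 14 Cajal-Retzius and subplate genes, 1 fell, the secreted factor Ndnf (log2 -0.79, SE 0.12, limma adjusted p 0.00778), and 13 did not pass; adjusted over the list alone, 3 rose and 2 fell. That list did not pass against other genes (camera adjusted p 0.708). Without control replicate 1 and without control replicate 2, 4 and 2 upper-layer genes fell, and 0 and 1 deep-layer genes; without cKO replicate 2, 4 genes of each list rose.

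Markers of ventrally born interneurons and clustered protocadherins were also lower. Of 22 measured interneuron and ventral genes, 7 fell, 2 rose and 13 did not pass (median -0.39); adjusted over the list alone, 14 fell and 3 rose. Lhx6, a transcription factor of migrating interneurons, went from 800.0 ± 7.74 to 419.6 ± 62.6 normalized counts (SD, n = 2 each; log2 -0.94, SE 0.11, limma adjusted p 0.00429), and Gad1 and Nxph1 each fell by 0.78 (SE 0.13 each). Sp8, a transcription factor that progenitors express, rose (log2 0.58, SE 0.091). Camera gave the list an adjusted p of 0.00296 (adjusted p = 0.424 with an estimated correlation). Of 53 measured protocadherins of the alpha, beta and gamma clusters, which carry neuronal cell identity at the membrane, 9 fell, 0 rose and 44 did not pass (median -0.27), and 9 fell when adjusted over the list alone. Pcdhga6 fell by 0.80 (SE 0.093), Pcdha11 by 1.13 (SE 0.19), Pcdha5 by 1.18 (SE 0.25) and Pcdhb14 by 0.75 (SE 0.16) on the log2 scale; the last 2 did not pass in the authors' test. As a set, these genes differed from the rest (camera adjusted p 2.85e-06; adjusted p = 0.321 with an estimated correlation). Alpha and gamma isoforms share 3' exons and beta genes are close copies, so single protocadherin counts are uncertain. Without control replicate 1 and without control replicate 2, 2 and 1 interneuron genes fell, and 2 and 0 protocadherins; without cKO replicate 2, 14 protocadherins fell.

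Genes of dividing cells were higher in the cKO. Of 39 measured cell cycle genes, 30 rose, 0 fell and 9 did not pass, with a median log2 change of 0.25; adjusted over the list alone, 36 rose and 1 fell. Mcm6, a subunit of the replicative helicase, went from 6044 ± 43.4 to 7817 ± 197 normalized counts (SD, n = 2 each; log2 0.37, SE 0.044, limma adjusted p 0.00429). Uhrf1, which maintains DNA methylation at replication, rose by 0.40 (SE 0.053), Mcm3 by 0.34 (SE 0.050) and the kinetochore motor Cenpe by 0.33 (SE 0.047). Set against all other genes, the list had a camera adjusted p of 5.09e-19 (adjusted p = 0.409 with an estimated correlation). Of 41 replication-dependent histone genes, 21 rose, 0 fell and 20 did not pass (median 0.22); adjusted over the list alone, 31 rose. Hist1h1b rose by 0.30 (SE 0.050), and Hist1h3f, Hist1h3d and Hist1h3b by 0.26, 0.26 and 0.25. The camera adjusted p was 1.33e-14, and the adjusted p = 0.372 with an estimated correlation; near-identical histone copies can share reads, so single members are uncertain. Against both controls the cell cycle median was 0.30 in cKO replicate 1 and 0.20 in cKO replicate 2, and the histone median 0.21 and 0.24. Of the cell cycle genes, 1 rose without control replicate 1, 0 without control replicate 2 and 17 without cKO replicate 1, and of the histone genes 0, 2 and 27.

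Radial glia genes were higher as well. Of 29 measured genes of these neural stem cells, 14 rose, 1 fell and 14 did not pass (median 0.16); adjusted over the list alone, 16 rose and 2 fell. Id4, an inhibitor of basic helix-loop-helix factors, went from 6019 ± 35.7 to 9660 ± 587 normalized counts (SD, n = 2 each; log2 0.68, SE 0.052, limma adjusted p 0.00244). Pdpn rose by 0.61 (SE 0.057) and Cdon by 0.30 (SE 0.047), and the receptor phosphatase gene Ptprz1 fell by 0.41 on the log2 scale (SE 0.061). Camera gave the list an adjusted p of 1.47e-05 (adjusted p = 0.372 with an estimated correlation). Of 18 intermediate progenitor genes, 4 rose, 3 fell and 11 did not pass, and the list did not pass against other genes (camera adjusted p 0.109), but passed with edgeR (adjusted p 0.0422; limma adjusted p = 0.454 with an estimated correlation). The 4 that rose were the proneural genes Neurog1 (log2 0.72, SE 0.11) and Neurog2 (log2 0.28, SE 0.042), Hes6 (log2 0.23, SE 0.050) and Btg2 (log2 0.20, SE 0.044), and adjusted over the list alone 8 rose and 5 fell. With TMM scaling and with quantile normalization 1 intermediate progenitor gene fell, and without cKO replicate 1 none did; without cKO replicate 2, 8 rose and 4 fell. Of 24 p53 and apoptosis genes, 2 rose and 3 fell, among them Plk2 (log2 -0.91, SE 0.14), Ccng1 (log2 -0.32, SE 0.067) and Pidd1 (log2 0.45, SE 0.097). That list did not pass against other genes (camera adjusted p 0.491), and 2 members rose and 4 fell when adjusted over the list alone. Without either control in turn, 2 radial glia genes rose, and 0 intermediate progenitor and 0 p53 genes rose or fell.

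Genes of the cortical hem, choroid plexus and dorsal midline, the medial edge of the cortex and a source of Wnt and Bmp signals, were higher in the cKO. Of 35 measured, 15 rose, 0 fell and 20 did not pass (median 0.33); adjusted over the list alone, 22 rose and 2 fell. Wnt8b, a Wnt ligand of the medial cortex, went from 861 ± 53.3 to 1161 ± 53.7 normalized counts (SD, n = 2 each; log2 0.43, SE 0.072, limma adjusted p 0.00901). The Wnt target Axin2 rose by 0.34 (SE 0.050), Lfng by 0.31 (SE 0.049) and Dkk3 by 0.31 (SE 0.045). As a set, these genes differed from the rest (camera adjusted p 1.26e-09; adjusted p = 0.321 with an estimated correlation). The median was 0.33 in cKO replicate 1 and 0.29 in cKO replicate 2. Of 15 measured Sonic hedgehog pathway genes, 6 rose, 1 fell and 8 did not pass (median 0.18); adjusted over the list alone, 8 rose and 3 fell. Those that rose were the co-receptor genes Gas1 (log2 0.38, SE 0.043, limma adjusted p 0.00429), Cdon and Boc (log2 0.30, SE 0.047, and 0.34, SE 0.059), the transducer Smo (log2 0.27, SE 0.046) and the transcription factor genes Gli2 and Gli3 (log2 0.44, SE 0.10, and 0.28, SE 0.056). Scube1 fell (log2 -0.29, SE 0.063). The transcriptional target Ptch1 had a log2 change of -0.21, which did not pass. Cdon and Gli3 are also in the radial glia list and Boc in the axon guidance list, so these lists are not independent. As a whole the pathway list was higher than other genes (camera adjusted p 0.00417; adjusted p = 0.372 with an estimated correlation). Without control replicate 1 and without control replicate 2, 0 and 0 hem genes and 1 and 0 hedgehog genes rose.

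Genes of axon guidance and callosal crossing changed in both directions. Of 50 measured, 13 fell, 6 rose and 31 did not pass; adjusted over the list alone, 15 fell and 6 rose. Sema3c, a guidance cue of the callosal midline, went from 4680 ± 242 to 2934 ± 189 normalized counts (SD, n = 2 each; log2 -0.67, SE 0.060, limma adjusted p 0.0027). Dscam fell by 0.63 (SE 0.063), the semaphorin receptor Nrp1 by 0.53 (SE 0.057) and the Slit receptor Robo2 by 0.48 (SE 0.052) on the log2 scale. Slit2, a repellent of commissural axons, rose (log2 0.40, SE 0.062, limma adjusted p 0.00778). As a whole the list did not pass against other genes (median -0.05, camera adjusted p 0.135). It passed with edgeR (adjusted p 0.0465), in the authors' test (adjusted p 0.0103), without control replicate 1 (adjusted p 0.0445) and without cKO replicate 1 (adjusted p 0.0175), always with the preset correlation (adjusted p = 0.596 with an estimated correlation over all 4 libraries). Fewer members rose and fewer fell when control replicate 1, control replicate 2 or cKO replicate 1 was left out. The rises no longer passed without either control. The list median was -0.050 without control replicate 1 and -0.022 without control replicate 2. It was -0.061 without cKO replicate 1 and -0.005 without cKO replicate 2.

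**Figure D1:**
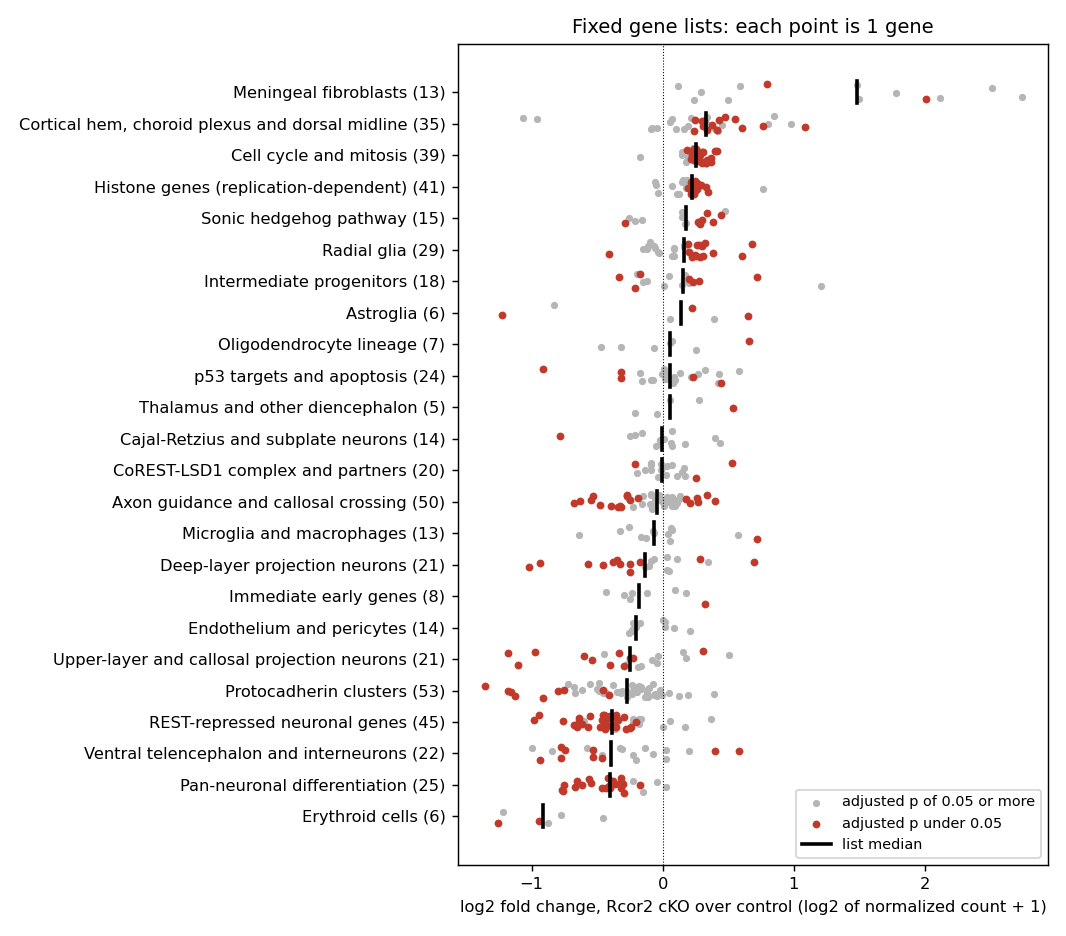
Each point is the log2 fold change of 1 gene (cKO over control, on log2 of normalized count + 1) in a list fixed before the data were examined, with the number of measured genes in brackets, and the black bar is the list median. Pan-neuronal genes sit at a median of -0.40 and cell cycle genes at 0.25; red points passed limma's adjusted p of 0.05.

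Markers of other tissues set cKO replicate 1 apart. Of 13 measured meningeal fibroblast markers, 2 rose, 0 fell and 11 did not pass, with a median log2 change of 1.48; adjusted over the list alone, 3 rose. Their median against both controls was 3.0 in cKO replicate 1 and 0.15 in cKO replicate 2. The fibrillar collagen gene Col3a1 had 334 and 308 normalized counts in the controls, 2842 in cKO replicate 1 and 282 in cKO replicate 2, and Igf2 had 703 and 675, 1406 and 671. Col1a1 (log2 2.01, SE 0.51, limma adjusted p 0.0354) and Dcn (log2 0.80, SE 0.21, limma adjusted p 0.0419) passed; with 2442 and 611 counts in the 2 cKO libraries, Col1a1 lay in part with the other meningeal genes. Neither passed with quantile normalization, in the authors' test or without either control, and Dcn did not pass with edgeR or without cKO replicate 1. The camera adjusted p for the list was 0.000371, and the adjusted p = 0.596 with an estimated correlation; without cKO replicate 1 it was 0.087. Of 6 measured erythroid markers, 2 fell and 4 did not pass (median -0.91), the heme synthesis gene Alas2 (log2 -1.26, SE 0.17) and the anion exchanger gene Slc4a1 (log2 -0.95, SE 0.22); adjusted over the list alone, 4 fell. Set against all other genes, the list had a camera adjusted p of 0.00369 (adjusted p = 0.579 with an estimated correlation). The erythroid median was -1.33 in cKO replicate 1 and -0.46 in cKO replicate 2. Across all tested genes, 128 were at least 2-fold higher in cKO replicate 1 than in cKO replicate 2, 1 of which was called higher in the cKO, and 56 were at least 2-fold higher in cKO replicate 2. Without control replicate 1 and without control replicate 2, 0 and 0 meningeal markers rose, and 1 and 0 erythroid markers fell; without cKO replicate 2, 10 meningeal markers rose and 6 erythroid markers fell.

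The remaining marker lists did not pass against other genes. Of 14 endothelial and pericyte markers, 0 passed with limma or edgeR, also when adjusted over the list alone, and 5 had an unadjusted p under 0.05 (camera adjusted p 0.203). Kdr and Rgs5, the most abundant of them, had log2 changes of 0.01 and -0.23, which did not pass. Of 13 microglia and macrophage markers, 1 rose, Mrc1 (log2 0.72, SE 0.17; camera adjusted p 0.885 for the list). Of 7 oligodendrocyte lineage markers, 1 rose, Pdgfra (log2 0.66, SE 0.18; camera adjusted p 0.885). Of 6 astroglial markers, Gja1 and Slc1a2 rose (log2 0.65, SE 0.10, and 0.22, SE 0.050) and Slc6a11 fell (log2 -1.23, SE 0.20); the list had a median of 0.14, a mean of -0.12 and an upward direction (camera adjusted p 0.528). Of 5 measured diencephalic markers, 1 rose, Lhx9 (log2 0.53, SE 0.083; camera adjusted p 0.34, but 0.0233 in the authors' test; limma adjusted p = 0.596 with an estimated correlation), and of 8 immediate early genes 1 rose, Ier2 (log2 0.32, SE 0.075; camera adjusted p 0.885). Adjusted over the list alone, 1 gene rose in each of the microglial, oligodendrocyte, diencephalic and immediate early lists, and 3 astroglial markers rose and 2 fell. Mrc1 and Pdgfra did not pass without cKO replicate 1, without control replicate 1 or without control replicate 2, nor did Mrc1 in the authors' test or Pdgfra with edgeR or quantile normalization. Ier2 did not pass in the authors' test or without either control. Sex-linked genes split the libraries by replicate number and not by genotype: Xist, the transcript of the inactive X chromosome, had 23.4 counts in control replicate 1 and 49.4 in cKO replicate 1, but 20334 and 21449 in replicates 2. The Y-linked gene Ddx3y had 2936 and 3211 counts in replicates 1 and 4.32 and 2.94 in replicates 2. None of the 5 sex-linked genes passed between genotypes with limma, edgeR, at an unadjusted p under 0.05 or adjusted over the list alone (camera adjusted p 0.774 for the list), and replicate 1 of each genotype has the pattern of a male and replicate 2 that of a female.

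**Figure D2:**
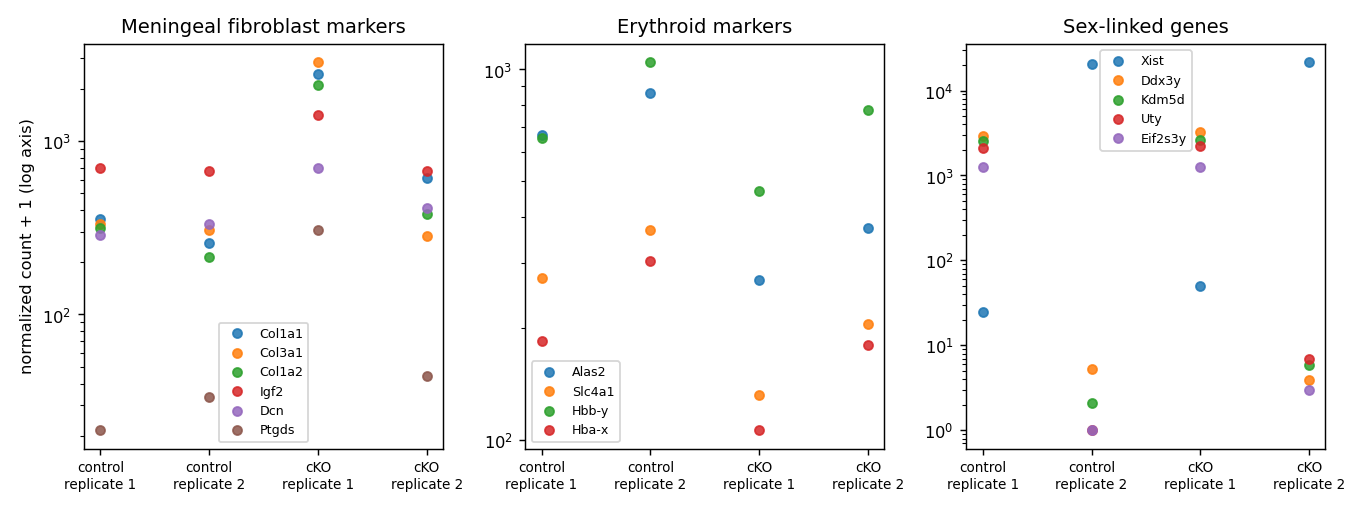
Normalized counts plus 1 (log axis) of meningeal, erythroid and sex-linked genes in each of the 4 RNA libraries, 1 point per gene and library. Col3a1 lies at 2842 in cKO replicate 1 and between 282 and 334 in the other 3 libraries, and Xist is high in both libraries of replicate 2.

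The ChIP-seq comparison asked where the Rcor2 antibody enriched chromatin over IgG in wild-type midline. The deposited table held 6995 peaks with a median width of 236 bp and a median fold enrichment over IgG of 4.0 (range 1.97 to 16.0), as the authors' caller gave it. By the authors' location classes, 2515 peaks (36.0%, 95% Clopper-Pearson interval 34.8 to 37.1) lay in gene bodies, 1642 (23.5%, 22.5 to 24.5) were intergenic, 1619 (23.1%, 22.2 to 24.2) lay at promoters and 1219 (17.4%, 16.5 to 18.3) were distal. The highest-scoring peak was a distal peak assigned to Lep, the leptin gene, on chromosome 6 (29036922 to 29037571, mm10), with 16.0-fold enrichment. Peaks in the bodies of Scfd2 (chromosome 5, 74349835 to 74350854; 15.6-fold) and of the reelin receptor gene Lrp8 (chromosome 4, 107816921 to 107817552; 13.8-fold) came next. A distal peak of Trim27 and an intergenic peak on chromosome 3 (51081758 to 51082843) followed with 14.3-fold and 14.0-fold, then promoter peaks of 1110001J03Rik and of the histone variant gene H2afy2 and distal peaks of Urm1, Tcf20 and Rnase12 with 11.6- to 13.7-fold. The adhesion gene Tenm4 carried 30 peaks, Auts2 27 and the transcription factor gene Nfia 14, the most of any gene. These are long genes, which span 739850, 1105888 and 540811 bp, and the counts were not scaled by span. Rcor2 itself had no peak, and Rest had 1 promoter peak (chromosome 5, 77266720 to 77266908) with 3.46-fold enrichment. The X chromosome held 33 peaks (0.472%), against 4.41% of protein-coding RefSeq genes, and 6 peaks lay on the Y chromosome. The input libraries had median heights of 9 and 9 at X peaks, against 13 and 12 at autosomal peaks. The first share covers all peaks, intergenic ones included, and was not tested, so it does not show that Rcor2 avoids the X chromosome.

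Heights at these peaks were compared between Rcor2, IgG and input libraries. The median height was 13 and 19 in the Rcor2 libraries, 4 and 3 in the IgG libraries and 13 and 12 in the input libraries. The median ratio of Rcor2 over IgG was 3.89, with 3.0 in replicate 1 and 5.29 in replicate 2. At 98.9% of peaks both Rcor2 libraries exceeded both IgG libraries, which follows in part from calling the peaks against IgG. Both input libraries exceeded both IgG libraries at 89.8% of peaks. Over input the median ratio was 1.33, with 1.0 in replicate 1 and 1.61 in replicate 2, and both Rcor2 libraries exceeded both input libraries at 40.3% of peaks (39.1 to 41.5). At the Lep peak the heights were 51 and 80 with Rcor2, 10 and 3 with IgG and 17 and 20 in input; at the Rest promoter they were 7 and 25, 3 and 8, and 23 and 19. Promoter peaks exceeded input at 30.4% (28.2 to 32.7), gene body peaks at 42.4% (40.5 to 44.4), distal peaks at 41.8% (39.0 to 44.7) and intergenic peaks at 45.7% (43.2 to 48.1). Across peaks, which are not independent replicates, heights of the 2 Rcor2 libraries had a Pearson r of 0.606 and a Spearman rho of 0.297, those of the 2 inputs 0.781 and 0.707, and those of the 2 IgG libraries 0.183 and 0.116. Heights were not scaled for library depth, which is unknown, so ratios between kinds of library carry an unknown factor, and no test between libraries was made.

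The last comparison asked whether genes with an Rcor2 peak were over-represented among the genes changed in the cKO. Of the 882 genes higher in the cKO, 318 (36.1%) had a peak assigned by the authors, against 19.9% of all other tested genes, an odds ratio of 2.27 (95% interval 1.96 to 2.63; Fisher's exact test, two-sided, p 8.64e-27). Of the 1188 lower genes, 300 (25.3%) had a peak, against 20.5% of all others, an odds ratio of 1.31 (1.14 to 1.51; Fisher's exact test, p 0.000165). Crocc, which encodes the ciliary rootlet protein, Car14, a carbonic anhydrase gene, and Pdpn were genes with promoter or distal peaks that rose, by 0.76 (SE 0.060), 1.41 (SE 0.11) and 0.61 (SE 0.057) on the log2 scale. Cdh8 (log2 -1.03, SE 0.081), Rbfox1, Nav3 (log2 -0.75, SE 0.069), Sema3c and Dscam were genes with peaks that fell. With mean expression level and gene span in a logistic model, the odds ratio was 1.99 (1.70 to 2.32) for higher genes and 0.776 (0.667 to 0.903) for lower genes, so the excess among lower genes turned into a deficit. Genes spanning over 200 kb fell in 24.6% of cases and genes under 10 kb in 5.33%. With promoter peaks alone, 163 higher genes (18.5%) and 86 lower genes (7.24%) had a peak, against 10.01% and 10.83% of all other tested genes, odds ratios of 2.04 (1.69 to 2.44; Fisher's exact test, p 2.35e-13) and 0.642 (0.506 to 0.807; p 6.21e-05). Higher and lower genes differed directly, with an odds ratio of 2.90 (2.18 to 3.88; Fisher's exact test, p 1.31e-14) for a promoter peak and 1.67 (1.37 to 2.03; p 1.48e-07) for any peak. This depended on the class of peak: gene body peaks, the largest class, were carried by 16.2% of higher and 16.3% of lower genes, with odds ratios against all other genes of 2.12 (1.75 to 2.57) and 2.20 (1.85 to 2.60; Fisher's exact test, p 2.93e-18). With level and span in the model these were 1.76 and 0.976. With 1 RNA library left out, the odds ratio of higher genes lay between 2.09 (without cKO replicate 2) and 3.67 (without control replicate 2). That of lower genes was 1.96 and 2.45 without control replicates 1 and 2, but 1.14 without cKO replicate 2. Without cKO replicate 1 it lay between 1.14 and 1.96. Only without cKO replicate 2 were the odds ratios of higher and lower genes below those with all libraries. The odds ratios without a control rest on far fewer called genes.

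**Figure D3:**
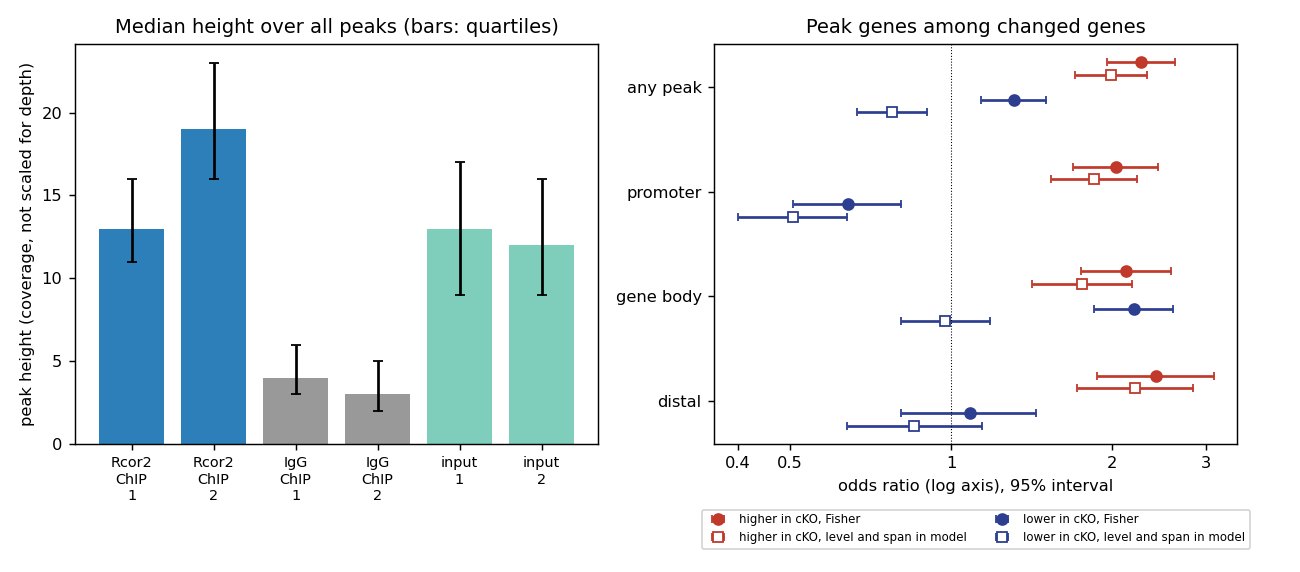
Left, the median peak height in each ChIP and input library (coverage, not scaled for depth), with lines from the lower to the upper quartile over all peaks. Right, odds ratios (log axis, 95% intervals) of carrying a peak for genes higher or lower in the cKO, by Fisher's test and with expression level and gene span in a logistic model; promoter peaks give 2.04 for higher and 0.642 for lower genes.

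Of the fixed lists, the largest excess of peaks by p-value was in the axon guidance genes. Of these, 33 of 50 carried a peak (66.0%, against 20.9% of tested genes, Fisher's exact test, adjusted p 1.73e-10). Among them were Sema3c and Nrp1 at the promoter (chromosome 5, 17574320 to 17574510, and chromosome 8, 128357919 to 128358206) and Dscam and Robo2 in the gene body. Peaks here were called over IgG. Both Rcor2 heights exceeded both input heights at the Robo2 peak (19 and 22 against 16 and 10). They did not at the peaks of Sema3c (5 and 22 against 8 and 16), Nrp1 (18 and 24 against 25 and 14) and Dscam (13 and 20 against 15 and 16). Of 29 radial glia genes 20 carried a peak (69.0%; adjusted p 4.13e-07 by Fisher's exact test), and of 21 deep-layer genes 16 (76.2%; adjusted p 7.31e-07), among them Sox5, Cdh13 and Ldb2. Hedgehog genes (8 of 15, adjusted p 0.028, Fisher's exact test) included a distal peak of Cdon with 8.99-fold enrichment (chromosome 9, 35403139 to 35403613), a promoter peak of Gas1 and a gene body peak of Boc. Both Rcor2 heights exceeded both input heights at the Cdon peak (35 and 39 against 20 and 19). They did not at those of Gas1 (7 and 20 against 16 and 17) and Boc (18 and 22 against 16 and 18). Of 25 pan-neuronal genes 11 carried a peak (adjusted p 0.0443, Fisher's exact test). None of 53 protocadherins had a peak (adjusted p 5.38e-05, Fisher's exact test). The named protocadherins lie close together on chromosome 18, and alpha and gamma isoforms overlap. Fisher's exact test takes such genes as independent, so its p-values for this list, also with promoter peaks alone, overstate the evidence. The cell cycle list did not stand out, with 6 of 39 (Fisher's exact test, adjusted p 0.728). Of the Rest-repressed genes, 12 of 45 carried a peak, an odds ratio of 1.38 (0.647 to 2.74; Fisher's exact test, adjusted p 0.497). With level and span in the model, the axon guidance (adjusted p 0.00133), radial glia (9.16e-06) and deep-layer (0.00133) lists still passed, the hedgehog (0.0899) and pan-neuronal (0.415) lists did not, and the intermediate progenitor (8 of 18, 0.0199) and hem (13 of 35, 0.0149) lists did. The protocadherins, with no peak gene, could not be tested in that model. With promoter peaks alone, the deep-layer (8 of 21, adjusted p 0.0215), histone (11 of 41, adjusted p 0.0341) and protocadherin (adjusted p 0.0459) lists passed Fisher's exact test. With the peaks above the median score, the hedgehog list did not pass (adjusted p 0.644) and the upper-layer list did (adjusted p 0.037).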

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

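Tests of promoter or gene body peaks alone, gene span, peaks above or not above input or ranked over it, ChIP libraries and ChIP ratios, edgeR with the block, removal of genes high in cKO replicate 1 and list members without each library were chosen after the results were seen; the rest were planned. The count of changed genes (2070, with 882 higher and 1188 lower) stayed between 1587 and 2095 under both pseudocounts and filters, TMM, quantile normalization, edgeR and the authors' deposited test. The count was 2144 (1048 higher, 1096 lower) with edgeR and the block and 2316 (987 and 1329) without genes high in cKO replicate 1. The excess of lower genes depended on the scaling, with 959 higher and 1048 lower under TMM and 858 and 895 under quantile normalization. Leaving out 1 RNA library gave 127 to 3463 genes, 53 to 1535 higher and 74 to 1928 lower; with fewer libraries the lone one is assumed to vary like the other group. At an adjusted p of 0.10 the count was 3235 (1396 higher, 1839 lower), and with at least a 1.5-fold change 436 (173 and 263). Rcor2 kept its direction in every setting, with log2 changes from -0.26 to -0.14 when 1 library was left out, and passed only without cKO replicate 2 and in the authors' deposited test (log2 -0.19, adjusted p 0.0444; range over its settings 0.00943 to 0.33). Of 13 list calls, 13 held under TMM, quantile normalization, edgeR and the authors' test, 12 without each library in turn (meningeal genes were lost without cKO replicate 1, adjusted p 0.087), 0 with an estimated correlation and 0 by fry. Of the changes among list results, 1 was weaker and 6 stronger (axon guidance, intermediate progenitor and diencephalic genes), and of those among named genes 137 were weaker, 1 stronger and 0 reversed; of 94 named calls, 53 and 62 were lost without control replicates 1 and 2, 5 and 0 without cKO replicates 1 and 2. With a library left out no named call could reverse, since the groups of each called gene did not overlap in value. The excess of peak genes among higher genes held in every setting. Among lower genes it did not pass at an unadjusted p of 0.05 (odds ratio 1.08, p 0.14), with expression level in the model (1.07, p 0.337) or with peaks only in the upper or lower part by rank over input (1.17, p 0.149, and 1.15, p 0.155), and reversed with promoter peaks alone (0.642) and with level and gene span (0.776); the causes were not tested. With promoter peaks alone 3 lists passed in place of 6, and with peaks above the median score 6, with upper-layer genes in place of hedgehog genes. The promoter share of peaks (23.1%) was 24.5% in the stronger part and 17.5% among peaks above input. Samples of the same replicate number deviated together (r = 0.242), but not without 5 sex-linked genes (r = -0.04), so apart from sex they seemed to share only a number; with a replicate block 2076 genes were called (895 higher, 1181 lower), 13 lists passed, Rest did not (adjusted p 0.0506), and no other named call changed. Distances to transcription start sites are not in the table, so the planned limits of 1 and 5 kb were not run. The 2014 genes under a mean of 10 were not tested, and ChIP depth was not analysed here.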

Other observations

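The gene families and the tests in this part were chosen after the results were seen, except the overlap with peaks in the stronger part by score, which was planned. Ionotropic glutamate receptor genes were lower in the cKO. Of 17 measured ionotropic glutamate receptor genes, 8 fell and 1 rose with limma, more falls than chance (Fisher's exact test, adjusted p 0.000269 over 20 tests of 10 families), with Gria1 (log2 -0.86, SE 0.10, limma adjusted p 0.00429), Grin2b (log2 -0.71, SE 0.063) and Grin1 (log2 -0.95, SE 0.13) among them, while Grik2 rose (log2 0.21, SE 0.056). Of 14 GABA-A receptor subunit genes, 5 fell and 2 rose (Fisher's exact test, adjusted p 0.0207 for falls; median 0.06), with Gabrb2 (log2 -0.55, SE 0.077) among those that fell and Gabra3 among those that rose (log2 0.43, SE 0.11). Of 17 cadherin genes 5 fell and 0 rose (Fisher's exact test, adjusted p 0.0343), led by Cdh8 (log2 -1.03, SE 0.081). Contactins (4 of 13 fell, adjusted p 0.0523), potassium channels (10 of 66, adjusted p 0.149), nicotinic receptors (2 of 7, adjusted p 0.198; 2 others rose, adjusted p 0.149, median 0.30) and metabotropic glutamate receptors (2 of 7, adjusted p 0.198) did not pass Fisher's exact test. Long genes fell more often (24.6% of those over 200 kb). With expression level and gene span in a logistic model, the falls of ionotropic glutamate receptors (adjusted p 0.00232) and GABA-A subunits (0.0102) passed and those of cadherins (0.114) did not. The nicotinic genes passed in both directions in that model (0.0334 for rises, 0.0358 for falls). Without control replicate 1 or without control replicate 2, the nicotinic genes that had risen or fallen no longer passed. Leaving out control replicate 1, control replicate 2 or cKO replicate 1, in that order, 5, 3 and 8 ionotropic glutamate receptor genes fell, 1, 1 and 5 GABA-A genes and 1, 2 and 3 cadherin genes; without cKO replicate 2 these counts were 7, 7 and 7.

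All 6 measured Dmrt genes, transcription factors that include medial cortical patterning genes, changed: 5 rose and 1 fell (Fisher's exact test, adjusted p 9.98e-05 for rises). Dmrta1 went from 191 and 241 normalized counts to 545 and 444 (log2 1.19, SE 0.14, limma adjusted p 0.00494), Dmrta2 rose by 0.43 (SE 0.062) and Dmrt3 by 0.28 (SE 0.062), and Dmrt2 fell by 1.41 on the log2 scale (SE 0.30). Of 12 retinoid handling genes, 5 rose and 0 fell (Fisher's exact test, adjusted p 0.00321), among them Crabp2, Cyp26b1, which degrades retinoic acid (log2 1.04, SE 0.14), Crabp1 (log2 0.44, SE 0.088) and Rarg (log2 0.45, SE 0.12). Of 38 collagen genes 7 rose and 1 fell (Fisher's exact test, adjusted p 0.0309), with Col4a6 (log2 0.55, SE 0.091) and Col26a1 (log2 0.68, SE 0.12) beside Col1a1. Meningeal markers, which include Col1a1 and the retinoic acid synthesis gene Aldh1a2, were higher in cKO replicate 1, and without that library 3 Dmrt genes, 3 retinoid genes and 5 collagens rose. When control replicate 1 or control replicate 2 was left out, 1 and 2 Dmrt genes, 2 and 2 retinoid genes and 1 and 0 collagens rose; without cKO replicate 2 these counts were 5, 8 and 18. With level and span in the model, the rises of Dmrt genes (adjusted p 0.000202), retinoid genes (8.48e-05) and collagens (0.00588) passed. With quantile normalization 4 Dmrt genes, 3 retinoid genes and 5 collagens rose.

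Neuronal genes were lower and cell cycle genes higher in the cKO, and several explanations were weighed. Dilution of the neural RNA of cKO replicate 1 by other tissue is argued against as the whole cause, since the pan-neuronal median was -0.30 in cKO replicate 2, which lacked the excess of meningeal markers, and since cell cycle genes moved the opposite way. A smaller share of neurons with every other cell type raised alike would move radial glia and vessel genes alike. The mean of radial glia genes exceeded that of endothelial and pericyte genes by 0.26 (SE 0.058 over genes). Against both controls, the medians in cKO replicates 1 and 2 were 0.20 and 0.14 for radial glia genes. For endothelial and pericyte genes they were -0.11 and -0.16. The lists thus differed in these libraries, but an SE over genes leaves out the spread between animals, so the explanation is not decided. A more medial dissection of the cKO tissue may also contribute, since the median of hem and dorsal midline genes was at least 0.29 in each cKO library. A gain of progenitors, lower transcription per neuron and an effect of the genotype on tissue shape stay open and were not tested.

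Meningeal genes were several-fold higher in cKO replicate 1. Meningeal tissue in the dissection of that library is a candidate explanation. Of 35 collagen genes outside the marker list, 25 were highest there (71.4%, 95% interval over genes 53.7 to 85.4, against 25% if no library differed). Collagens that rose in both cKO libraries would also raise this share above 25%, so it does not single out that explanation. In cKO replicate 2 the median of the markers was 0.15 above the controls (SE over genes 0.13). That is 1 library, and the markers moved together (estimated correlation 0.937), so the SE is too small. A rise with the genotype of 0.5 or more on the log2 scale therefore cannot be decided from it. A different stage or litter of the tissue in that library was not tested.

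Genes with an Rcor2 peak were over-represented among genes higher in the cKO. Mean expression level and gene span are argued against as the whole cause, since the odds ratio was 1.99 (1.70 to 2.32) with both in the model. Chromatin that input libraries recover as well may add to the pattern. With peaks ranked by Rcor2 over input within each replicate, which needs no library depth, genes with peaks only in the lower part gave 1.78 (1.45 to 2.17) and genes with peaks only in the upper part 1.54 (1.23 to 1.91), intervals that overlap. Release of genes that Rcor2 represses would also give such an excess. Genes with peaks in the stronger part by score gave 2.24 (1.89 to 2.65) and genes with weaker peaks alone 1.71 (1.39 to 2.09), which overlap too. Each odds ratio was taken against all other tested genes, those with the other kind of peak included. Overlap of such intervals is not a test of a difference, so the last 2 explanations cannot be told apart here.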
